A study of Mus musculus with 22 samples.

How the data were processed

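The data are mRNA sequencing libraries of whole bone marrow from 22 mice. Per the labels' protocols, LSK cells (lineage-negative, Sca-1-positive and Kit-positive marrow cells, the fraction that holds blood stem and progenitor cells) of Cas9 knock-in mice received pairs of single guide RNAs (sgRNAs) and were transplanted into irradiated C57BL/6 mice. Marrow was taken at signs of leukaemia or after 6 months, and the labels used here do not say which applied to which mouse. A guide against luciferase (sgLuc), which has no target in the mouse genome, served as the control and as the partner guide in the single-gene groups. The groups are sgLuc (6 libraries), sgRunx1 + sgLuc (3), sgEzh2 + sgLuc (3), sgBcor + sgLuc (3), sgEzh2 + sgRunx1 (4) and sgBcor + sgRunx1 (3), and each group was read from the sample title. The replicate number in the title and that in the description differ for 4 libraries, and the title's number is used.

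Read counts per Ensembl gene and FPKM (fragments per kilobase of gene length, scaled to the counted reads of the library) were deposited. Per the submitters' processing notes, fastp, HISAT2 and HTSeq were used with the mouse build mm9. Their versions, the order and options of the steps, the use of strand and the annotation release are not given in the sources used here. The deposited counts are whole numbers for 47069 genes and carry no normalization. The deposited FPKM values equal the count divided by the library total and by 1 length per gene in all 14383 genes with a read in every library, within a relative tolerance of 1e-06, so in these genes they add only that length to the counts. Since the use of strand in the authors' counting is not given, reads of genes that overlap on opposite strands, such as Xist and Tsix, cannot be told apart, and reads of near-identical genes (the stefin A genes Stfa1, Stfa2, Stfa2l1, Stfa3 and BC100530, the complement genes C4a and C4b, and the carboxylesterases of the Ces2 family) can be split between copies or left out. Gene positions come from GENCODE M21 (GRCm38), a later build than the mm9 of the processing notes, and no position was converted. Of the deposited IDs, 46574 (98.95%) matched that annotation, and 67 symbols were shared by more than 1 ID.

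Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group (default minimum count 10), which left 17659 genes, and libraries were scaled by TMM. One quasi-likelihood model (glmQLFit and glmQLFTest, robust) with a mean for each of the 6 groups was fitted to all 22 libraries, with 16 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p (FDR) under 0.05 within a comparison. The SE given with a log2 fold change is approximate: the absolute log2 fold change divided by the square root of the F statistic of the edgeR test. Levels are TMM-scaled CPM (counts scaled to library size), given as mean ± SD over the mice of a group. The comparisons were each of the 5 edited groups against sgLuc, each double against each of its singles, the doubles against each other, and 2 interactions, each of which tests whether a double differs from the sum of its single effects on the log2 scale.

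The gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated from the residuals and with fry. The 32 lists held 582 symbols, of which 10 were absent from the count table. They covered cell types (erythroid; neutrophil secondary and tertiary granule; primary granule; monocyte and macrophage; megakaryocyte and platelet; stem and progenitor; B cell progenitor; mature B cell; plasma cell; T and NK cell; dendritic cell; eosinophil, basophil and mast cell; stroma, bone and endothelium), regulators (Hoxa, Hoxb and cofactors, PRC2 and PRC1 subunits, fetal program, RUNX family and partners, INK4 and CDK inhibitors) and processes (heme synthesis, MHC class II, cell cycle, MYC and ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, cholesterol synthesis, type I interferon response, inflammation and NF-kB, immediate early and heat shock, p53 targets, ERK feedback), with sex-linked markers as a check. The lists, the tests, the comparisons, the rule for the genes named and most alternatives were fixed before the data were examined. Besides Runx1, Ezh2 and Bcor, the genes named were the 6 with the largest log2 fold change in each direction in comparisons against sgLuc, and the 3 in each direction elsewhere, among called genes with a mean of at least 4 CPM over all libraries and, outside the interactions, no overlap of CPM between the groups. Predicted genes, pseudogenes and antigen receptor segments were passed over. List members were named in order of p.

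Total counts ran from 30023722 to 57175449 per library. Where every library of a group had 0 counts of a gene, the fold is given as a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with its exact 95% counting interval. Such bounds and intervals, and those of shares of counts, cover counting error only. No pair of replicates agreed within sampling noise (lowest chi-square per degree of freedom 14.76), so each library was counted as 1 mouse. The labels do not name the mice, and p-values measure the spread between these libraries. The labels give no batch. The same replicate numbers occur in several groups, and whether they pair the libraries is reported with the alternatives.

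The edgeR test was tested on simulated counts for 17659 genes with the library sizes of these groups and 1 mean per gene over all libraries. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery at lower levels was not measured. In the simulation of sgRunx1 + sgLuc against sgLuc it recovered 52 of 100 genes changed by 1 on the log2 scale and 84 of 100 changed by 2, with 0.73% false calls. In that of sgEzh2 + sgRunx1 against sgRunx1 + sgLuc it recovered 47 and 80 of 100, with 5.93% false calls. The DESeq2 1.42.0 test recovered 62 and 92 of 100 in the first simulation with 15.8% false calls, and 59 and 92 of 100 in the second with 24.5%. Each simulation was 1 draw with the spread per gene estimated by edgeR, a setting that can favour edgeR. These shares therefore do not rank the tests or measure false calls in the real data.

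The alternatives were DESeq2 size factors, the DESeq2 test, limma voom with sample quality weights, the deposited FPKM as log2(FPKM + 0.5) with limma trend, library sizes without haemoglobin, immunoglobulin and S100a8 and S100a9 genes, other low-count filters, a test against an absolute log2 fold change of 1 (glmTreat), fits of only the groups compared, the replicate number as a block, and leaving out each library of the groups compared in turn. Leaving out sgEzh2 + sgLuc replicate 3 in the comparisons that do not use its group and leaving out the genes on X and Y were chosen after seeing the data, while leaving out sgLuc replicate 3, which held mixed sex-linked reads, was among the planned omissions. Against TMM, the DESeq2 size factors moved all genes by at most 0.02 (log2) in any comparison of a pair of groups. The FPKM scaling, which has no such correction, moved them by 0.18 in sgEzh2 + sgRunx1 against sgBcor + sgRunx1, by −0.17 in sgBcor + sgRunx1 against sgBcor + sgLuc, by 0.12 in sgEzh2 + sgLuc against sgLuc, and by under 0.1 in the others. The values of 2 genes that the rules for named genes and list members would give are not reported here.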

Results

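Whole bone marrow of 22 transplanted mice was profiled by mRNA sequencing to compare marrow grown from LSK cells edited with guides against Runx1, Ezh2 or Bcor, alone or with the Runx1 guide. The groups were sgLuc (6 mice), sgRunx1 + sgLuc (3), sgEzh2 + sgLuc (3), sgBcor + sgLuc (3), sgEzh2 + sgRunx1 (4) and sgBcor + sgRunx1 (3). Runx1 encodes a transcription factor of blood cell development, Ezh2 the histone H3 lysine 27 methyltransferase of Polycomb complex PRC2, and Bcor a corepressor of a variant Polycomb complex PRC1. The sgLuc libraries held 30023722 to 33191421 counts, except replicate 5 with 57175449. Totals were 39690068 to 45085176 in sgRunx1 + sgLuc, 43269269 to 46351232 in sgEzh2 + sgLuc and 39923331 to 45680170 in sgBcor + sgLuc. They were 34784989 to 53836084 in sgEzh2 + sgRunx1 and 39630303 to 43821283 in sgBcor + sgRunx1.

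The first principal component held 34.7% of the variance and the second 15.8%, and sgEzh2 + sgLuc replicate 3 lay apart from all other libraries. Transcripts of granulocytes and their precursors were scarce in it: S100a8, a calcium-binding protein of neutrophils, stood at 63.2 CPM against 6840 to 25100 in the other 21 libraries, the lysozyme gene Lyz2 at 158 against 6200 to 14700, and the myeloperoxidase gene Mpo at 8.24 against 1570 to 8360. T cell transcripts were abundant, with the receptor chain Cd3d at 484 CPM against 0.111 to 16.7 and the transcription factor Tcf7 at 909 against 0.357 to 41.1. Each count of called genes per comparison is therefore also given from a fit without this library, as are the counts of members of the lists described where they moved by over 1.5 times. This setting was chosen after seeing the data for the comparisons that do not use its group.

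**Figure D1:**
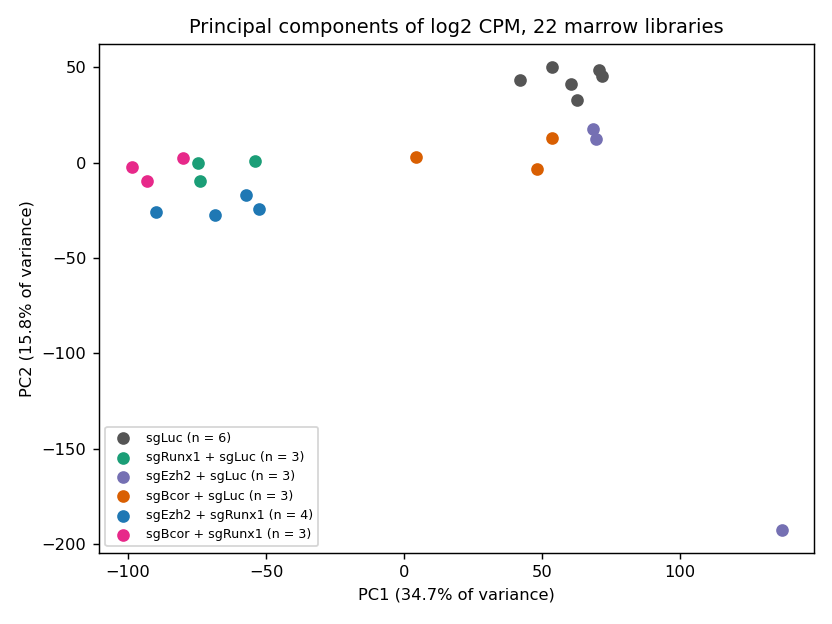
Principal components of log2 CPM over 17659 genes, with the first component (34.7% of the variance) on the horizontal and the second (15.8%) on the vertical axis and 1 point per library, coloured by group. sgEzh2 + sgLuc replicate 3 lies apart from the other 21 libraries.

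The targeted genes were examined first. On GRCm38 (GENCODE M21) Runx1 (ENSMUSG00000022952) lies on chromosome 16 at 92601466 to 92826149, Ezh2 (ENSMUSG00000029687) on chromosome 6 at 47530139 to 47595341 and Bcor (ENSMUSG00000040363) on chromosome X at 12036740 to 12160355, all on the minus strand. The guide sequences and the exons they target are not given in the sources used here. Cas9 insertions and deletions need not lower an mRNA, and whole marrow can hold unedited cells, so a level that did not fall does not contradict a label.

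Ezh2 mRNA was lower in both groups with its guide. It stood at 99.8 ± 8.19 CPM in sgLuc (SD, n = 6; 88.2 to 109.9), at 59.5, 70.5 and 57.6 CPM in the replicates of sgEzh2 + sgLuc, and at 50.7, 43.9, 48.5 and 77.1 CPM in those of sgEzh2 + sgRunx1. The log2 fold changes against sgLuc were −0.67 (SE 0.169, edgeR FDR 0.0212) and −0.86 (SE 0.154, edgeR FDR 0.00127). Without sgEzh2 + sgLuc replicate 3 the first was −0.62 and missed the threshold (edgeR FDR 0.147, 0.0176 to 0.147 over the omissions). Ezh2 was also lower in sgBcor + sgRunx1 (66.6 to 88.7 CPM) than in sgBcor + sgLuc (93.3 to 159.7), by −0.71 on the log2 scale (edgeR FDR 0.0212), a call that ended without sgBcor + sgRunx1 replicate 1, sgBcor + sgLuc replicate 1 or sgBcor + sgLuc replicate 3 (edgeR FDR 0.0659 to 0.123).

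Runx1 mRNA was not lower in any group with its guide. It stood at 94.2 ± 5.14 CPM in sgLuc (n = 6), 115 ± 21.4 in sgRunx1 + sgLuc (n = 3; 136, 115 and 93.1 in its replicates), 118 ± 15.2 in sgEzh2 + sgRunx1 (n = 4; 99.7 to 136) and 114 ± 19.2 in sgBcor + sgRunx1 (n = 3; 92.9 to 130.2), and none of these groups differed from sgLuc by the edgeR test (FDR 0.226, 0.119 and 0.186). The level was 78.6 ± 11.3 in sgEzh2 + sgLuc and 117 ± 18.6 in sgBcor + sgLuc. Against sgEzh2 + sgLuc it was higher in sgEzh2 + sgRunx1 (log2 fold change 0.58, edgeR FDR 0.015), a call that ended without sgEzh2 + sgLuc replicate 3 (FDR 0.0677) or sgEzh2 + sgRunx1 replicate 1 (FDR 0.0542).

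Bcor mRNA was higher, not lower, in sgBcor + sgLuc. It stood at 60.1 ± 5.85 CPM in sgLuc (n = 6) and at 126, 111 and 200.2 CPM in sgBcor + sgLuc (log2 fold change 1.28, SE 0.265, edgeR FDR 0.0139), and without sgBcor + sgLuc replicate 3 the difference was 0.98 and missed the threshold (edgeR FDR 0.128, 0.000991 to 0.128 over the omissions). In sgBcor + sgRunx1 replicate 1 held 159 CPM and replicates 2 and 3 held 62.8 and 78.6 (log2 fold change 0.74, edgeR FDR 0.0717). sgEzh2 + sgLuc replicate 3 held 155 CPM against 64.6 and 65.0 in the other replicates of its group.

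**Figure D2:**
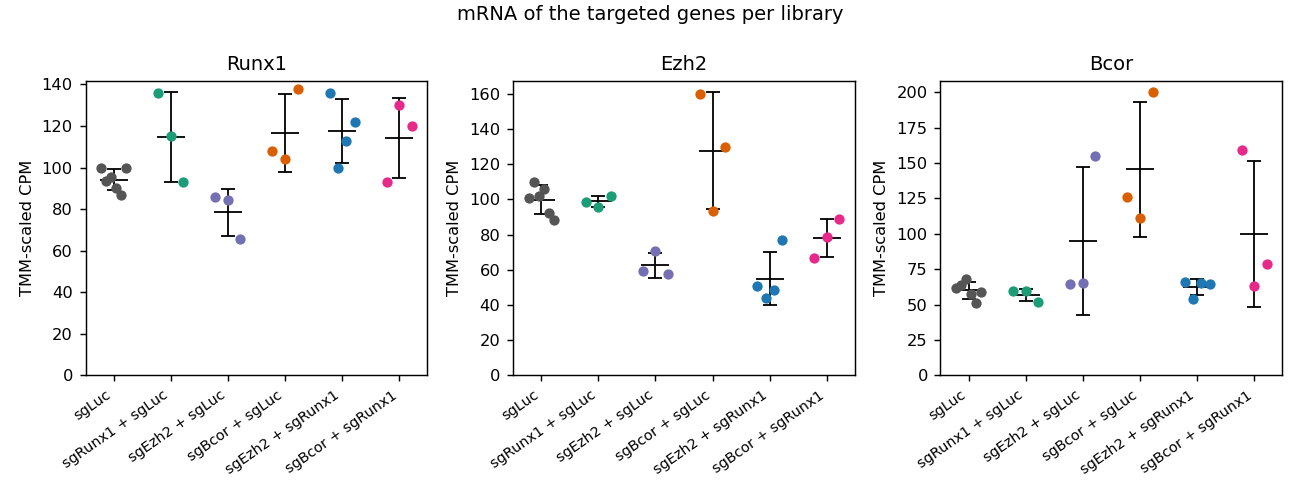
Runx1, Ezh2 and Bcor in TMM-scaled CPM on the vertical axis, by group on the horizontal axis, with 1 point per library and bars for the group mean and SD. Ezh2 is at 43.9 to 77.1 in the 7 libraries with its guide and at 88.2 to 109.9 in sgLuc.

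Sex separated the control group from all others. Y-linked transcripts were present in all 6 sgLuc libraries, with the RNA helicase gene Ddx3y at 40.1 to 68.7 CPM of the unscaled library total, and no library of the other groups held a read of Ddx3y, Eif2s3y, Kdm5d or Uty. Xist, the RNA of the inactive X chromosome, stood at 264 to 737 in these 16 libraries and at 0.0308 to 2.83 in sgLuc, except replicate 3 with 140 beside the lowest Ddx3y level. Eif2s3y, Ddx3y and Kdm5d were accordingly at least 3720-fold, 2330-fold and 1010-fold lower in every edited group than in sgLuc. The edgeR call of Xist (log2 fold changes 4.45 to 4.73) ended without any of the 3 libraries of sgRunx1 + sgLuc in that comparison (FDR 0.0608 to 0.0773), without sgLuc replicate 2, 4, 5 or 6 or sgEzh2 + sgLuc replicate 3 in that of sgEzh2 + sgLuc (0.0522 to 0.139), and without any of the 3 libraries of sgBcor + sgLuc or sgLuc replicate 1, 2, 4, 5 or 6 in that of sgBcor + sgLuc (0.054 to 0.132), while without sgLuc replicate 3 the difference rose to between 8.40 and 8.69 in these comparisons. The sex-linked list was called in all 5 comparisons against sgLuc, with 1 member higher and 4 lower in each (camera adjusted p at most 5.59e-15, adjusted p at most 9.23e-06 with an estimated correlation, and the same counts adjusted over the list alone). The sex of the mice, or a batch or donor genotype that followed it, cannot be separated from the guides in any comparison with sgLuc or in the interactions. The labels give neither sex nor batch.

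In marrow with the Runx1 guide alone, lymphoid genes fell and some platelet genes rose against sgLuc. The mature B cell list held 10 members that fell and 2 that did not pass, among them the CD20 gene Ms4a1 (log2 fold change −6.12) and Fcer2a, the low-affinity IgE receptor (−5.07). Of the 10 plasma cell genes 7 fell, among them the immunoglobulin joining chain Jchain (−7.01), and 3 did not pass. Camera called this list in all 5 comparisons against sgLuc, with and without the Runx1 guide. Of 17 B cell progenitor genes 8 fell, such as the receptor chain Cd79a (−4.79), and of 20 T and NK cell genes 3 fell, Klrb1c (−3.18), Klrd1 (−2.74) and the granzyme Gzma (−4.69), and 17 did not pass. Of 16 megakaryocyte and platelet genes 7 rose, among them the platelet tubulin Tubb1 (3.73) and the adhesion receptor Selp (2.37), and 9 did not pass. In the fit without sgEzh2 + sgLuc replicate 3, 7 T and NK cell genes fell.

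Among single genes, C4b, a complement component, rose from 3.11 ± 1.29 CPM in sgLuc to 140.0 ± 86.6 in sgRunx1 + sgLuc (log2 fold change 5.49, SE 0.871, edgeR FDR 0.00105), and the chemokine gene Ccl24 from 0.458 ± 0.285 to 17.4 ± 2.14 (5.25). Hmga2, an architectural chromatin protein of fetal stem cells, rose from 0.311 ± 0.348 to 8.66 ± 3.05 CPM (4.81), Emp1, a membrane protein gene, by 3.99 and the heme-binding protein gene Hebp1 by 3.52. The last pair lies 22.3 and 22.1 Mb from Gt(ROSA)26Sor, a locus often used for knock-in alleles. Apart from Y-linked genes, the largest falls were in Cyp11a1, Prss34 and Fcer1a. Prss34, a basophil protease, fell from 386 ± 158 to 0.332 ± 0.406 CPM (−10.20). Fcer1a, the alpha chain of the IgE receptor, had 2 counts in the 3 libraries (ratio 1310, 95% counting interval 362 to 10800), and Cyp11a1, a steroid synthesis enzyme, had none and was at least 545-fold lower. C4b shares sequence with C4a, and its level is uncertain to that extent.

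Between sgRunx1 + sgLuc and sgLuc the edgeR test called 1434 genes, 488 higher and 946 lower. Adjusted over the list alone, 11 mature B cell, 10 plasma cell, 10 B cell progenitor and 5 T and NK cell genes were lower and 9 platelet genes higher. Camera called these lists (adjusted p 3.68e-12, 3.45e-10, 5.89e-07, 3.07e-07 and 3.16e-06, in this order). With an estimated correlation the adjusted p was 0.147, 0.0457, 0.48, 0.48 and 0.48. Of 17 eosinophil, basophil and mast cell genes 6 were lower and 11 did not pass (adjusted over the list alone, 1 higher and 8 lower; camera adjusted p 0.000733, adjusted p = 0.48 with an estimated correlation), and Jund alone rose among 17 immediate early and heat shock genes (1 adjusted over the list alone; camera adjusted p 0.00115, adjusted p = 0.574 with an estimated correlation). In sgLuc replicate 4 the mean log2 CPM was 4.21 for the immediate early and heat shock list (7.16 to 8.31 in the other sgLuc libraries) and −0.0283 for the platelet list (1.20 to 1.66). The count was 562, 515 and 735 without sgRunx1 + sgLuc replicate 1, 2 and 3, and 2647 without sgEzh2 + sgLuc replicate 3, which enters through the shared spread, with 1431 of the 1434 genes among them. Sex is confounded with this comparison.

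In marrow with the Ezh2 guide alone, T and NK cell genes were higher than in sgLuc, with 11 of 20 members called, such as Tcf7 at 329 ± 503 CPM against 11.8 ± 4.04 (log2 fold change 4.8), and none of the 20 was called without sgEzh2 + sgLuc replicate 3. Raver2, an RNA-binding protein gene, rose from 0.743 ± 0.304 to 26.8 ± 41.8 CPM (log2 fold change 5.17, SE 0.733, edgeR FDR 0.000611), and of the 6 genes with the largest rise it alone, beside the 3 Y-linked genes among those that fell, kept its call in every omission (1.87, edgeR FDR 0.025, without that replicate). The macrophage complement genes C1qa, C1qb and C1qc were lower, at 5.71 ± 3.32, 8.33 ± 5.30 and 5.63 ± 3.76 CPM against 42.2 ± 25.7, 47.9 ± 26.9 and 34.3 ± 22.1 (−2.88, −2.52 and −2.61).

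The edgeR test called 1456 genes between sgEzh2 + sgLuc and sgLuc, 1111 higher and 345 lower. Without sgEzh2 + sgLuc replicate 3 it called 191, 146 higher and 45 lower, of which 165 were shared. The count was 836 and 934 without sgLuc replicates 1 and 6, and 2624 and 2384 without sgEzh2 + sgLuc replicates 1 and 2. Without replicate 3 the calls ended for the T cell adaptor Sh2d1a (5.01 with it, 2.11 without, FDR 0.374), Tcf7 (1.71, FDR 0.168), the CD3 zeta chain Cd247 (4.63 with it, 1.36 without, FDR 0.492), Dzip1 (4.50 with it, 1.84 without, FDR 0.187), C1qa (−2.52, FDR 0.273), C1qb (−2.10, FDR 0.302) and C1qc (−2.27, FDR 0.294). The C1q calls ended also without sgLuc replicate 1, 2 or 3 or sgEzh2 + sgLuc replicate 1, and those of C1qb and C1qc without sgLuc replicate 5 (edgeR FDR from 0.0525). Sex is confounded with this comparison.

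Of the lists, T and NK cell (13 higher adjusted over the list alone) had a camera adjusted p of 0.000141 in sgEzh2 + sgLuc against sgLuc, and mature B cell, with 4 of 12 members higher such as Cr2 (3.48) and Fcrl1 (1.78), had 0.000241 (9 adjusted over the list alone). Both kept the camera call without replicate 3 (0.0134 and 0.0293) with 0 members called by edgeR. With an estimated correlation the adjusted p was 0.496 for both. Of 44 cytosolic ribosomal protein genes 17 were higher and 27 did not pass (30 adjusted over the list alone; camera adjusted p 7.83e-10, adjusted p = 0.496 with an estimated correlation), and 3 were higher without replicate 3 (camera adjusted p 0.175). Lists called with no more than 3 members passing and not called without replicate 3 were neutrophil secondary and tertiary granule (0 of 18 members; camera adjusted p 2.67e-06, and 0.865 without it), cell cycle (0 of 32; 0.000628 and 0.207), stem and progenitor (1 of 19, Cd27 higher; 0.0041 and 0.78), megakaryocyte and platelet (2 of 16, Clec1b and Itga2b lower; 0.00407 and 0.403) and RUNX family and partners (0 of 15; 0.0182 and 0.175), each with as many adjusted over the list alone. Their adjusted p with an estimated correlation was 0.496, 0.549, 0.496, 0.496 and 0.496. Camera called the plasma cell list lower, against the direction of mature B cell, with 1 of 10 members past the threshold, Xbp1, also over the list alone (adjusted p 0.0343, and 0.0221 without replicate 3, adjusted p = 0.496 with an estimated correlation). The eosinophil, basophil and mast cell list was also called lower, with Prg2 and Cpa3 lower, Il4 higher and 14 of 17 that did not pass (1 higher and 4 lower adjusted over the list alone; camera adjusted p 9.38e-05, and 0.000719 without replicate 3, adjusted p = 0.496 with an estimated correlation). Of 19 monocyte and macrophage genes the 3 C1q genes fell and 16 did not pass (6 lower adjusted over the list alone; camera adjusted p 9.06e-08, and 0.00641 without replicate 3, adjusted p = 0.496 with an estimated correlation). Of 16 glycolysis genes Hk1 fell (−0.54) and 15 did not pass (2 lower adjusted over the list alone; camera adjusted p 0.000349, adjusted p = 0.496 with an estimated correlation). The primary granule list was called with 0 of 10 members passing, also over the list alone (camera adjusted p 0.000241, and 0.0252 without replicate 3, adjusted p = 0.496 with an estimated correlation). Of 24 MYC and ribosome biogenesis genes 3 were higher, Gnl3, Nop56 and Npm1 (8 adjusted over the list alone; camera adjusted p 0.0126, adjusted p = 0.738 with an estimated correlation), and without replicate 3 camera called the list lower (0.00987). Of all members of these lists edgeR called only the 3 ribosomal ones without replicate 3.

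In marrow with the Bcor guide alone, homeobox genes of the Hoxa and Hoxb clusters were higher than in sgLuc. Of 19 Hoxa, Hoxb and cofactor genes 4 rose, Hoxb7 (log2 fold change 4.15), Hoxa5 (2.57), Hoxa2 (3.28) and Hoxb8, and 15 did not pass. Hoxb8 had 3 counts in all of sgLuc (ratio 427, 95% counting interval 146 to 2070). Emp1 rose from 3.65 ± 2.19 to 111 ± 40.1 CPM (4.91, SE 0.604, edgeR FDR 0.000175), the zinc finger gene Zfp827 from 0.972 ± 0.621 to 13.6 ± 6.06 (3.8) and the protocadherin gene Pcdh7 from 0.396 ± 0.432 to 4.69 ± 0.779 (3.50). Chst1, a carbohydrate sulfotransferase, fell from 14.6 ± 8.63 to 0.553 ± 0.0794 CPM (−4.71) and the proteoglycan gene Vcan from 32.3 ± 23.6 to 1.39 ± 0.767 (−4.53).

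Of the 10 plasma cell genes 5 fell in sgBcor + sgLuc, such as Tnfrsf17, the receptor BCMA (−4.73), and Jchain (−3.91), and 5 did not pass. Of 13 ERK feedback genes, which ERK signalling induces, its negative regulators Dusp4 (2.05) and Spry1 (2.01) rose and 11 did not pass. None of 19 erythroid genes passed over all genes, and 9 were higher adjusted over the list alone. Without sgEzh2 + sgLuc replicate 3 in the fit, 12 Hox, 4 ERK feedback and 4 erythroid genes rose. Over the list alone, 15 Hox, 6 ERK feedback and 6 plasma cell genes passed. The camera adjusted p was 5.54e-08 for the Hox list, 1.18e-06 for plasma cells, 2.06e-06 for the erythroid list and 0.000192 for ERK feedback. The adjusted p with an estimated correlation was 0.146, 0.133, 0.59 and 0.133.

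For sgBcor + sgLuc against sgLuc the edgeR test called 558 genes, 348 higher and 210 lower. The count was 326 without sgLuc replicate 1, 210 and 120 without sgBcor + sgLuc replicates 1 and 3, and 1484, the 558 among them, without sgEzh2 + sgLuc replicate 3. Without sgBcor + sgLuc replicate 3 the calls of the myosin gene Myh10 (3.34 with it, 1.98 without, edgeR FDR 0.102), Dzip1 (3.78 with it, 2.08 without, FDR 0.237) and Tceal8 (−4.16 with it, FDR 0.113 without) ended, and that of Tceal8 ended also without replicate 2 (FDR 0.0601). That of Vcan ended without any of the 3 libraries of the group or without sgLuc replicate 1, 2, 4 or 5 (edgeR FDR 0.0562 to 0.163). Sex is confounded with this comparison.

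In sgEzh2 + sgRunx1 marrow, lymphoid genes fell against sgLuc, and the complement gene C4b and the acute-phase gene Saa3 rose. C4b rose from 3.11 ± 1.29 to 892 ± 516 CPM (log2 fold change 8.16, SE 0.943, edgeR FDR 3.64e-05; n = 4), Saa3 from 0.951 ± 0.761 to 73.9 ± 104 (6.28), Ccl24 to 24.3 ± 9.45 (5.73), Hmga2 to 11.8 ± 2.76 (5.25) and Emp1 to 93.8 ± 17.5 (4.68). Ms4a1 fell from 45.7 ± 22 to 0.0651 ± 0.119 CPM (−9.43) and Prss34 to 0.0417 ± 0.0664 (−12.84), and Cyp11a1, with 0 counts, was at least 785-fold lower. All 13 named genes, Ezh2 and the sex-linked ones included, kept their call in each of the 11 omissions.

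Of 17 B cell progenitor genes 10 fell in sgEzh2 + sgRunx1, such as Cd79a (−5.60) and the transcription factors Pax5 (−6.23) and Ebf1 (−5.94), and of 12 mature B cell genes 9 fell. Of 20 T and NK cell genes 7 fell, among them Cd8b1 (−3.77) and Thy1 (−2.57), and the receptor chain Cd3e had 2 counts (ratio 454, 95% counting interval 126 to 3750). Of the 10 plasma cell genes 7 fell, and of 9 MHC class II genes 6 fell, such as Cd74 (−1.87) and H2-Ab1 (−1.78). Adjusted over the list alone, 14, 10, 15, 7 and 7 members of these lists were lower, the camera adjusted p was 4.01e-10, 1.11e-12, 9.76e-10, 2.02e-07 and 1.36e-05. With an estimated correlation the adjusted p was 0.333, 0.13, 0.333, 0.13 and 0.383. The edgeR test called 1787 genes, 712 higher and 1075 lower, and with the FPKM scaling the split was 1118 higher and 919 lower. The count was 1176 and 1180 without sgEzh2 + sgRunx1 replicates 2 and 3, and 3163, with 1785 of the genes among them, without sgEzh2 + sgLuc replicate 3. In that fit 13 T and NK cell genes fell. The neutrophil secondary and tertiary granule list (18 genes) and the MYC and ribosome biogenesis list (24), with 0 members called in the fit of all libraries, then had 10 lower and 1 higher, and 12 higher. Sex is confounded with this comparison.

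In sgBcor + sgRunx1 marrow, lymphoid and antigen presentation genes fell against sgLuc. Of 9 MHC class II genes 8 fell, among them the transactivator Ciita (log2 fold change −4.11) and Cd74 (−3.58). Of 12 mature B cell genes 10 fell, of 20 T and NK cell genes 9, of 10 plasma cell genes 8, of 17 B cell progenitor genes 8 and of 14 dendritic cell genes 7, such as Ms4a1 (−7.13), Irf4 (−5.23) and the integrin Itgax (−2.46). The stefin A genes Stfa2 (75.7 ± 89.7 against 3.05 ± 1.75 CPM, 4.62), Stfa3 (94.1 ± 87.3 against 4.85 ± 2.13, 4.27) and BC100530 (64.4 ± 66.5 against 2.66 ± 1.08, 4.59) rose, with reads that near-identical copies can share. C4b rose to 169 ± 122 CPM (5.76, SE 0.879, edgeR FDR 0.000373), the carboxylesterase gene Ces2g to 74.6 (15.3 to 191.7; 4.50) and Hmga2 to 6.78 ± 1.04 (4.46).

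Prss34 had 1 count in sgBcor + sgRunx1 (ratio 43800, 95% counting interval 7860 to 1730000), and Fcer1a and Cr2, the complement receptor of B cells, had 0 and were at least 807-fold and 217-fold lower than in sgLuc. Of 19 Hoxa, Hoxb and cofactor genes 5 rose, such as Hoxb5 (5.18) and Hoxb7 (3.56), and the cofactor Pbx3 fell (−1.28). Of 14 genes of stroma, bone and endothelium 4 fell, such as Lpl (−3.97) and Col1a2 (−5.46). Of 32 oxidative phosphorylation genes 5 rose by 0.36 to 0.53, such as Atp5o (0.46), and 27 did not pass.

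Adjusted over the list alone, 8 MHC class II, 10 mature B cell, 16 T and NK cell, 8 plasma cell, 14 B cell progenitor, 9 dendritic cell and 7 stromal genes were lower, 5 oxidative phosphorylation genes higher, and 8 Hox genes higher and 1 lower in sgBcor + sgRunx1. The camera adjusted p was 8.28e-09, 7.34e-11, 3.17e-09, 5.44e-09, 3.98e-06, 3.99e-07, 0.00377, 1.89e-05 and 9.99e-05 in this order. With an estimated correlation the adjusted p was 0.208, 0.202, 0.259, 0.0769, 0.439, 0.259, 0.225, 0.544 and 0.33. The edgeR test called 2547 genes, 835 higher and 1712 lower. The count was 1427 without sgBcor + sgRunx1 replicate 3 and 4133, with 2544 of the genes among them, without sgEzh2 + sgLuc replicate 3. In that fit 14 T and NK cell and 7 stromal genes fell, and 9 Hox and 9 oxidative phosphorylation genes rose (1 of each list fell). It also called 5 of 18 neutrophil secondary and tertiary granule, 4 of 10 primary granule and 12 of 44 cytosolic ribosomal protein genes higher, against 0, 0 and 3 in the fit of all libraries. The call of Stfa2 ended without replicate 3 (edgeR FDR 0.0541) and that of Ces2g without replicate 1 (edgeR FDR 0.0639). Sex is confounded with this comparison.

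**Figure D3:**
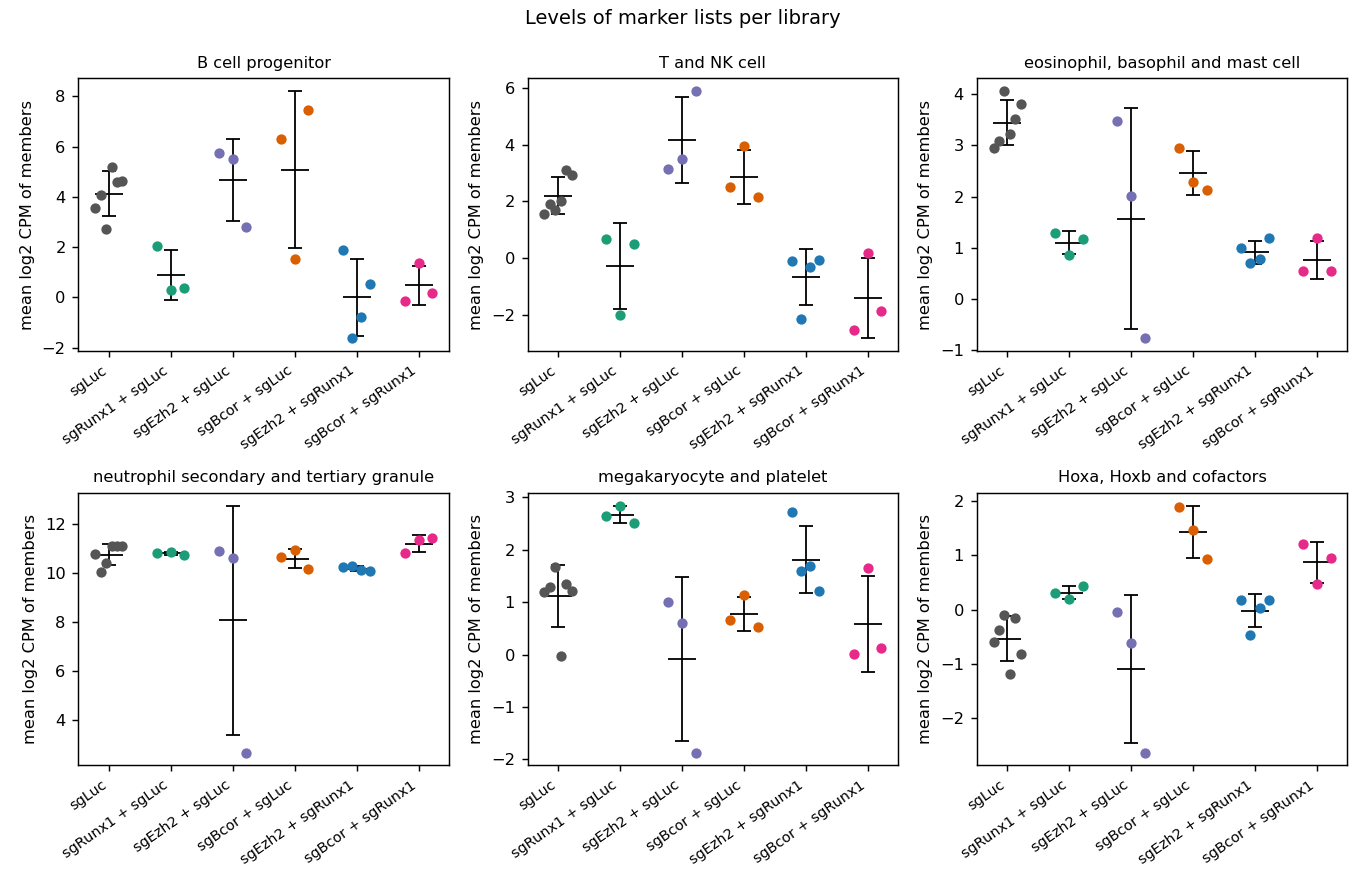
Mean log2 CPM of the members of 6 gene lists (vertical axes) by group (horizontal axes), with 1 point per library and bars for the group mean and SD. The B cell progenitor level is at 2.73 to 5.20 in the sgLuc libraries, and the neutrophil granule level of sgEzh2 + sgLuc replicate 3 is 2.64.

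The effect of adding the Ezh2 guide to the Runx1 guide was compared within mice that all lacked Y-linked reads. Lamc1, a laminin chain, rose from 2.86 ± 0.173 CPM in sgRunx1 + sgLuc to 47.1 ± 21.5 in sgEzh2 + sgRunx1 (log2 fold change 4.04, edgeR FDR 0.00958), the actin nucleator Spire1 from 1.70 ± 0.286 to 15.3 ± 1.33 (3.17) and the centromere protein gene Cenpv from 2.64 ± 0.679 to 18.4 ± 4.74 (2.80). Igf2r, the mannose 6-phosphate receptor, fell from 49.4 ± 3.44 to 22 ± 1.52 CPM (−1.17, SE 0.123, edgeR FDR 0.000113), Zfand2a, a stress-induced zinc finger gene, from 70.7 ± 1.08 to 36 ± 2.13 (−0.97) and Parp16 from 5.43 ± 0.117 to 2.89 ± 0.302 (−0.91). Ezh2 itself stood at −0.84 and missed the threshold (edgeR FDR 0.0524).

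In all, 33 genes were called between these groups by the edgeR test, 24 higher and 9 lower. DESeq2 size factors gave 25 and 17, as did library sizes without abundant genes, and the FPKM scaling 159 and 26. The count was 6, 5 and 7 without sgRunx1 + sgLuc replicates 1, 2 and 3, 21 without sgEzh2 + sgRunx1 replicate 2, and 570, with all 33 among them, without sgEzh2 + sgLuc replicate 3. Of the 6 named genes only Igf2r kept its call in each of the 8 omissions. The calls of Lamc1, Spire1 and Cenpv ended without any replicate of sgRunx1 + sgLuc (edgeR FDR 0.0669 to 0.105), and those of Zfand2a and Parp16 without any library of either group (0.0696 to 0.181). Camera called 6 lists, none with a member past the threshold over all genes. They were erythroid and megakaryocyte and platelet (lower, adjusted p 0.00211 for both), cell cycle and ERK feedback (lower, 0.00791 and 0.00575), and MYC and ribosome biogenesis and oxidative phosphorylation (higher, 0.00575 and 0.0238). Adjusted over the list alone only ERK feedback had calls (3 lower), and with an estimated correlation the adjusted p was 0.867 for it and 0.978 for the others. Without sgEzh2 + sgLuc replicate 3 in the fit, 4 neutrophil secondary and tertiary granule and 2 primary granule genes were lower and 3 MYC and ribosome biogenesis genes higher.

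Adding the Runx1 guide to the Ezh2 guide lowered lymphoid genes in mice without Y-linked reads. Ms4a1 fell from 156 ± 115 CPM in sgEzh2 + sgLuc to 0.0651 ± 0.119 in sgEzh2 + sgRunx1 (log2 fold change −11.20, edgeR FDR 3.68e-05; −10.39 without sgEzh2 + sgLuc replicate 3). Of 12 mature B cell genes 11 fell, of 17 B cell progenitor genes 13 and of 20 T and NK cell genes 19. C4b rose from 3.92 ± 3.52 to 892 ± 516 CPM (7.83, edgeR FDR 0.000736), Saa3 from 0.34 ± 0.311 to 73.9 ± 104 (7.77) and Ccl24 from 0.673 ± 0.342 to 24.3 ± 9.45 (5.17). Cd3e had 2 counts in sgEzh2 + sgRunx1 (ratio 8570, 95% counting interval 2370 to 70700), a ratio that rests on the 286 CPM of sgEzh2 + sgLuc replicate 3, and Izumo1r, the folate receptor 4 of regulatory T cells, fell by 11.25 with that replicate and by 4.52 without it.

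The edgeR test called 2228 genes between sgEzh2 + sgRunx1 and sgEzh2 + sgLuc, 702 higher and 1526 lower. The FPKM scaling gave 1080 and 1450. The count was 1383 without sgEzh2 + sgRunx1 replicate 2, and 1701 without sgEzh2 + sgLuc replicate 3, of which 1241 were shared. Adjusted over the list alone, 12 mature B cell, 15 B cell progenitor and 20 T and NK cell genes were lower. The camera adjusted p was 2.69e-15, 7.10e-09 and 9.07e-15. The adjusted p with an estimated correlation was 0.201, 0.515 and 0.285. Without sgEzh2 + sgLuc replicate 3 edgeR still called 10, 14 and 16 members lower. Of 16 platelet genes 4 rose, such as Selp (3.54) and Ppbp (4.14), and 12 did not pass (7 adjusted over the list alone; camera adjusted p 2.83e-05, adjusted p = 0.515 with an estimated correlation), and 2 rose without sgEzh2 + sgLuc replicate 3. The 18 neutrophil secondary and tertiary granule genes held 0 calls, also over the list alone, and camera called the list higher (adjusted p 0.000848, adjusted p = 0.683 with an estimated correlation) but lower without that replicate (adjusted p 0.00203, with 7 members lower and 1 higher).

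The effect of adding the Bcor guide to the Runx1 guide was likewise compared in mice without Y-linked reads. Zfp827 rose from 0.0673 ± 0.0543 CPM in sgRunx1 + sgLuc to 8.05 ± 1.65 in sgBcor + sgRunx1 (log2 fold change 6.86, SE 1.02, edgeR FDR 0.00393), the glycosyltransferase gene Galnt3 from 4.37 ± 0.707 to 14.9 ± 2.14 (1.77) and Cenpv to 9.70 ± 4.71 (1.88). Casc4 fell from 1.99 ± 0.448 to 0.0377 ± 0.0654 CPM (−5.67), the actin-binding protein gene Afap1 from 11.4 ± 2.04 to 0.959 ± 0.809 (−3.57) and Mrc1, the mannose receptor of macrophages, from 41.2 ± 1.91 to 3.86 ± 2.32 (−3.42). Of 16 platelet genes Tubb1 fell (−4.92) and 15 did not pass, of 9 MHC class II genes Ciita fell (−2.63), and of 20 inflammation and NF-kB genes Tnfaip3, an inhibitor of NF-kB, fell (−1.90).

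Between sgBcor + sgRunx1 and sgRunx1 + sgLuc the edgeR test called 219 genes, 74 higher and 145 lower. A fit of only these groups called 6 genes, 4 of them among the 219, and the fit with the replicate block called 98. The FPKM scaling gave 42 and 163. The count was 24 and 21 without sgRunx1 + sgLuc replicates 1 and 2, 18 without sgBcor + sgRunx1 replicate 3, and 913, with all 219 among them, without sgEzh2 + sgLuc replicate 3. Of the 6 named genes Zfp827 alone kept its call in each of the 7 omissions. Omission of sgBcor + sgRunx1 replicate 3 ended the calls of Casc4 (FDR 0.0626), Mrc1, Afap1, Galnt3 and Cenpv, omission of sgRunx1 + sgLuc replicate 1 or 2 those of the latter 4, of sgRunx1 + sgLuc replicate 3 those of Afap1, Galnt3 and Cenpv, of sgBcor + sgRunx1 replicate 1 those of Afap1 and Galnt3, and of replicate 2 those of Galnt3 and Cenpv (edgeR FDR 0.0593 to 0.232). The fit without sgEzh2 + sgLuc replicate 3 called 3 platelet, 3 MHC class II and 2 inflammation genes lower. Over each list alone 6 platelet, 5 MHC class II and 3 inflammation genes were lower. The camera adjusted p was 1.84e-07, 1.01e-05 and 0.00291. With an estimated correlation the adjusted p was 0.914, 0.914 and 0.948.

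Adding the Runx1 guide to the Bcor guide lowered lymphoid and erythroid genes in mice without Y-linked reads. Of 17 B cell progenitor genes 14 fell, such as Ebf1 (log2 fold change −8.64) and Cd79a (−6.31), of 12 mature B cell genes 10 fell, of 20 T and NK cell genes 11 fell, and of 19 erythroid genes 9 fell, such as the erythropoietin receptor Epor (−3.40) and the blood group gene Rhd (−3.8). The B cell progenitor level of sgBcor + sgLuc was 6.29 and 7.43 in replicates 1 and 3 and 1.54 in replicate 2. Of 16 glycolysis genes Tpi1 (0.57), Pkm (0.76) and Gpi1 (0.86) rose. Ccl24 rose from 0.0672 ± 0.0582 CPM in sgBcor + sgLuc to 7.46 ± 6.81 in sgBcor + sgRunx1 (6.71, SE 0.897, edgeR FDR 0.000358), Entpd3, an ectonucleotidase, to 23.7 ± 36.6 (5.79) and Saa3 to 13.9 ± 15.5 (5.74). Prss34 had 1 count (ratio 9610, 95% counting interval 1720 to 379000), and Cr2 and Fcer1a had 0 and were at least 234-fold and 203-fold lower.

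The edgeR test called 2161 genes between sgBcor + sgRunx1 and sgBcor + sgLuc, 612 higher and 1549 lower. The FPKM scaling gave 251 and 1786. The count was 1227 without sgBcor + sgRunx1 replicate 3, 1138 and 1093 without sgBcor + sgLuc replicates 1 and 3, and 3827, with 2154 of the genes among them, without sgEzh2 + sgLuc replicate 3. In that fit 18 T and NK cell genes fell and 7 glycolysis genes rose, as did 7 neutrophil secondary and tertiary granule, 7 primary granule and 9 cytosolic ribosomal protein genes (0, 1 and 0 in the fit of all libraries). The call of Entpd3 ended without sgBcor + sgRunx1 replicate 3 or sgBcor + sgLuc replicate 2 or 3 (edgeR FDR 0.0555 to 0.165), and that of Saa3 without sgBcor + sgRunx1 replicate 1 or any replicate of sgBcor + sgLuc (0.067 to 0.0925). Adjusted over the list alone, 16 B cell progenitor, 10 mature B cell, 20 T and NK cell and 13 erythroid genes were lower and 6 glycolysis genes higher. The camera adjusted p was 5.39e-08, 7.35e-09, 1.21e-10, 9.45e-07 and 0.000453. With an estimated correlation the adjusted p was 0.413 for each.

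The doubles were compared with each other in mice without Y-linked reads. Casc4 was higher in sgEzh2 + sgRunx1 (6.00 ± 1.71 CPM) than in sgBcor + sgRunx1 (0.0377 ± 0.0654; log2 fold change 7.27), as were Spire1 (15.3 ± 1.33 against 0.32 ± 0.27; 5.58, SE 0.569, edgeR FDR 3.66e-05) and the tight junction gene Tjp1 (25.4 ± 5.96 against 0.716 ± 0.639; 5.14). Zfp827 was lower (0.185 ± 0.116 against 8.05 ± 1.65; −5.39), as were the stefin A genes Stfa1 (9.82 ± 6.78 against 105 ± 100; −3.41) and Stfa2l1 (34.6 ± 19.1 against 248 ± 46.2; −2.85), whose reads near-identical copies can share. Of 9 MHC class II genes Ciita (2.41), Cd74 (1.71) and H2-Aa (1.70) were higher, and of 23 type I interferon response genes Ifi44 (3.96), Mx1 (2.15) and Mx2 (1.98) were higher.

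Between the doubles the edgeR test called 1245 genes, 853 of them higher in sgEzh2 + sgRunx1, and the FPKM scaling gave 1258 and 129. The count was 726 without sgEzh2 + sgRunx1 replicate 4, 462 without sgBcor + sgRunx1 replicate 3, and 2726, with all 1245 among them, without sgEzh2 + sgLuc replicate 3. In that fit 14 of 18 neutrophil secondary and tertiary granule genes were lower, where the fit of all libraries called 0. The call of Stfa2l1 ended without any library of either double (edgeR FDR 0.064 to 0.126), and that of Stfa1 without any of these but sgBcor + sgRunx1 replicate 1 (0.0516 to 0.245). Over each list alone, 5 MHC class II and 3 interferon genes were higher. The camera adjusted p was 0.0026 and 0.0404. The adjusted p with an estimated correlation was 0.916 for both. The interferon call ended without sgEzh2 + sgRunx1 replicate 1, 2 or 4 or sgBcor + sgRunx1 replicate 1 or 3 (camera adjusted p 0.0516 to 0.349).

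**Figure D4:**
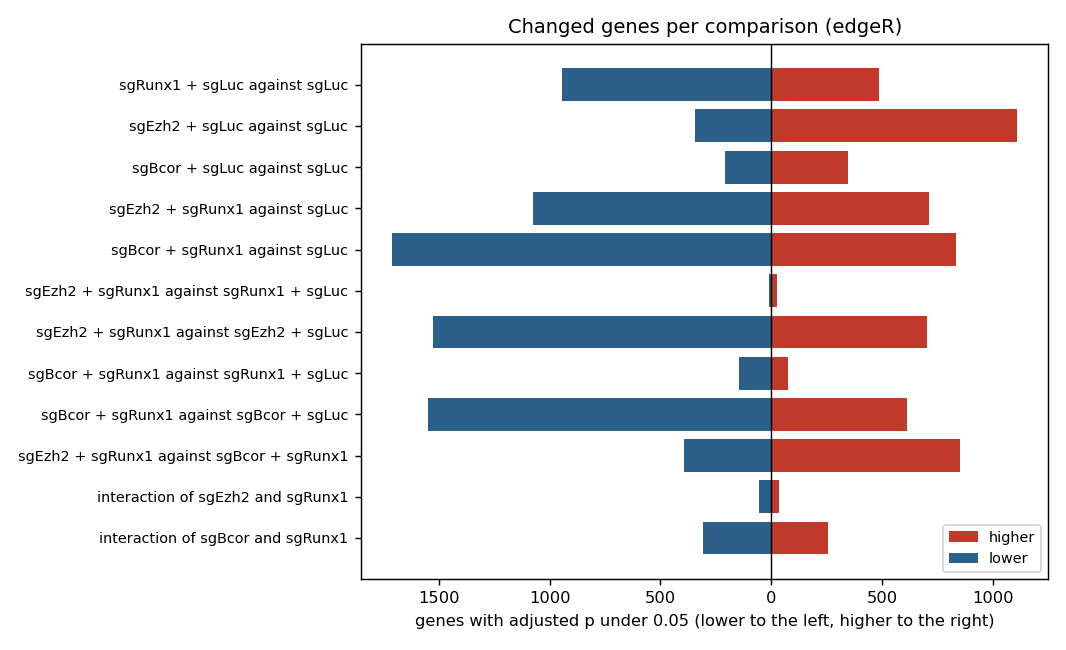
Number of genes called at an edgeR FDR under 0.05 (horizontal axis, bars) in each comparison and interaction (vertical axis), higher to the right and lower to the left of 0. The largest count is 2547 for sgBcor + sgRunx1 against sgLuc and the smallest 33 for sgEzh2 + sgRunx1 against sgRunx1 + sgLuc.

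The interactions tested whether a double differed from the sum of its singles. For Ezh2 and Runx1, Chst1 was higher than the sum (3.53 ± 0.879 CPM in the double, 1.85 ± 0.0779 and 2.98 ± 1.31 in the singles with the Runx1 and the Ezh2 guide, 14.6 ± 8.63 in sgLuc; log2 difference 3.22, edgeR FDR 0.0355), as were the transferrin gene Trf (2.52) and the protease gene Ctsc (2.05). Sytl2 (−6.48) and the interleukin 12 receptor gene Il12rb1 (−4.36) were lower than the sum, and their levels in sgEzh2 + sgLuc rest on replicate 3 (maxima of 63.4 and 57.6 CPM). For Bcor and Runx1, Emp1 was lower than the sum (17.8 ± 10.4 CPM in the double, 58.5 ± 28.1 and 111 ± 40.1 in the singles, 3.65 ± 2.19 in sgLuc; −6.63, SE 0.969, edgeR FDR 0.00305), as were Casc4 (−6.36) and the interferon-induced GTPase gene Iigp1 (−8.50), while Vcan (8.07), the apolipoprotein gene Apoc2 (4.51) and Oas1g (4.16) were higher.

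For Ezh2 and Runx1 the edgeR test called 93 genes, 36 above and 57 below the sum, and the FPKM scaling gave 92 and 91. The count was 42, 35 and 42 without sgLuc replicates 1, 2 and 5, 6, 11 and 44 without sgRunx1 + sgLuc replicates 1, 2 and 3, 205, 322 and 144 without sgEzh2 + sgLuc replicates 1, 2 and 3 (68 shared genes in the last), and 39, 22, 28 and 24 without sgEzh2 + sgRunx1 replicates 1, 2, 3 and 4. None of these 5 genes kept its call in all 16 omissions. The calls of all 5 ended without any replicate of sgRunx1 + sgLuc or sgEzh2 + sgRunx1 or without sgLuc replicate 2, those of Sytl2 and Il12rb1 also without sgEzh2 + sgLuc replicate 3 or any replicate of sgLuc, and those of Chst1, Trf and Ctsc also without sgLuc replicate 1 or 5, of Trf without replicate 3 or 6 and of Ctsc without replicate 4 (edgeR FDR 0.0511 to 0.191). Both interactions contain sgLuc and are confounded with sex. Chst1 was lower and Emp1 higher in every edited group than in sgLuc. Such an offset of sgLuc alone gives an interaction of the sign observed for each, positive for Chst1 and negative for Emp1.

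For Bcor and Runx1 the edgeR test called 568 genes, 258 above and 310 below the sum, and the FPKM scaling gave 153 and 482. The count was 338, 377 and 342 without sgLuc replicates 1, 4 and 5, 89 and 104 without sgRunx1 + sgLuc replicates 1 and 2, 357 without sgBcor + sgRunx1 replicate 2 and 357 without replicate 3, 167 and 158 without sgBcor + sgLuc replicates 1 and 3, and 1660, with 567 of the genes among them, without sgEzh2 + sgLuc replicate 3. Emp1 and Casc4 kept their call in all 16 omissions. The calls of Vcan, Apoc2 and Oas1g ended without sgRunx1 + sgLuc replicate 1 or 2, that of Iigp1 without sgRunx1 + sgLuc replicate 1 or sgBcor + sgRunx1 replicate 2 or 3, and, among replicates of sgBcor + sgLuc, that of Vcan ended without replicate 1, of Apoc2 without replicate 3, of Oas1g without replicate 2 or 3 and of Iigp1 without replicate 2 (edgeR FDR 0.0541 to 0.0891). Of 19 erythroid genes Epor was below the sum (−3.44) and 18 did not pass, with 11 below it adjusted over the list alone (camera adjusted p 6.25e-08, adjusted p = 0.619 with an estimated correlation), and 7 below it over all genes without sgEzh2 + sgLuc replicate 3. Of 32 oxidative phosphorylation genes 6 were above it, such as Ndufa8 (1.02), with 10 adjusted over the list alone (camera adjusted p 6.35e-08, adjusted p = 0.79 with an estimated correlation).

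Calls against sgLuc overlapped most among the 3 groups with the Runx1 guide. sgRunx1 + sgLuc and sgEzh2 + sgRunx1 shared 235 higher and 588 lower genes, with 2 called in opposite directions, against 19.7 and 57.6 for independent lists. In 20 simulations of unchanged groups against shared simulated controls the number was 0. Groups without changes have hardly any calls to share, so this 0, here and below, is no reference for the overlap. The log2 fold changes correlated across genes with r = 0.812 (0.359 in the simulations; genes are not independent replicates), and their covariance was 1.86 against a simulated 0.12. With sgLuc split so that each comparison had its own 3 controls, the medians were 84 higher and 341 lower shared genes and the mean r was 0.719. All these controls held Y-linked reads, so a difference of sgLuc from every edited group stays shared in the split, here and below. For sgRunx1 + sgLuc and sgBcor + sgRunx1 the shared genes were 234 and 644 (independent 23.1 and 91.7, simulated at most 0; 93.5 and 389 with split controls), with r 0.781 (simulated 0.326, split 0.696) and a covariance of 2.03 against 0.123. For the doubles they were 259 and 655 (independent 33.7 and 104, simulated at most 0; 102.5 and 401.5 with split controls), with r 0.745 (simulated 0.356, split 0.667) and a covariance of 2.04 against 0.12. Groups with no targeted gene in common also shared calls. For sgRunx1 + sgLuc and sgBcor + sgLuc they were 112 higher and 108 lower genes (independent 9.62 and 11.2), with 18 in opposite directions. With split controls these were 28 and 35.5. The lowest r was between sgEzh2 + sgLuc and sgBcor + sgRunx1, 0.0593 (simulated 0.329, split −0.00689), with a covariance of 0.109 against 0.122, 155 shared higher and 66 shared lower genes (independent 52.5 and 33.4) and 201 in opposite directions.

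The Runx1 calls were also examined in comparisons without sgLuc. Of the 1434 genes called in sgRunx1 + sgLuc against sgLuc, 80.6% had the same sign in sgEzh2 + sgRunx1 against sgEzh2 + sgLuc, with 626 called in both in the same direction and 13 in opposite ones, and 74.3% had it in sgBcor + sgRunx1 against sgBcor + sgLuc (509 and 29). The first check includes sgEzh2 + sgLuc replicate 3, without which 1241 of the 2228 calls of its second comparison remained. It was not repeated without that library, and the share of same sign over all tested genes was not computed. Of the 1456 genes called for the Ezh2 guide, of which only 165 were also called without sgEzh2 + sgLuc replicate 3, 62.8% had the same sign in sgEzh2 + sgRunx1 against sgRunx1 + sgLuc (14 and 0). Of the 558 called for the Bcor guide, 42.8% had it in sgBcor + sgRunx1 against sgRunx1 + sgLuc (17 and 12).

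All 5 comparisons against sgLuc called 79 genes in the same direction, 51 higher and 28 lower. Simulated unchanged groups gave 0 in each of 20 runs, but without changes hardly any other outcome was possible, so this 0 is no reference. Of the 79 genes, 10 lay on X or Y (12.7%, against 3.21% of tested genes). Many of the 51 higher members were predicted genes or pseudogenes, such as Tpt1-ps3 and Rps13-ps2. The mitochondrial genes mt-Atp6, mt-Co2 and mt-Co3 were also among the higher members. In 67 of the 79 the 16 edited libraries did not overlap the 6 sgLuc libraries, a separation that the choice of these genes favours. Gt(ROSA)26Sor, a noncoding RNA on chromosome 6 at 113067428 to 113077333 (GRCm38), stood at 4.47 to 11.7 CPM in sgLuc and at 0.178 to 1.36 in the other libraries. Emp1 stood at 0.709 to 6.04 and 6.90 to 153, and Hebp1 at 1.94 to 7.46 and, with overlap, 2.56 to 124.

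**Figure D5:**
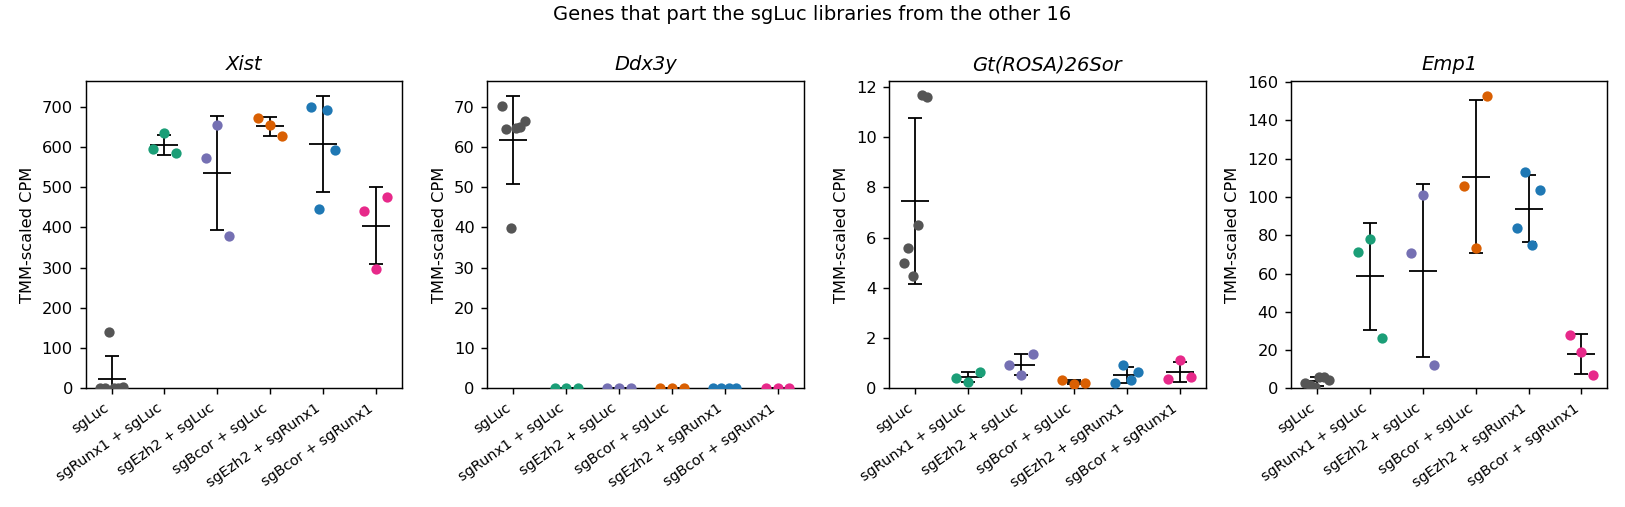
Xist, Ddx3y, Gt(ROSA)26Sor and Emp1 in TMM-scaled CPM (vertical axes) by group (horizontal axes), with 1 point per library and bars for the group mean and SD. No edited library holds a Ddx3y read, and Gt(ROSA)26Sor is at 4.47 to 11.7 in sgLuc and at 0.178 to 1.36 elsewhere.

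Camera called 140 of 384 list tests with the preset correlation and 8 with an estimated correlation, of which 7 were the sex-linked list and 1 the plasma cell list in sgRunx1 + sgLuc against sgLuc (0.0457). With the preset correlation, plasma cell and eosinophil, basophil and mast cell were called in all 5 comparisons against sgLuc. These calls are not particular to a guide, and sex is confounded with each. No comparison or interaction called the lists heme synthesis (lowest camera adjusted p 0.076), PRC2 and PRC1 subunits (0.0942), fetal program (0.132), cholesterol synthesis (0.357), p53 targets (0.186) or INK4 and CDK inhibitors (0.0571).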

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

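All tests of explanations below, and the splits of the libraries for the 10 comparisons, were chosen after the result was seen; the splits for both interactions were planned before.

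A library far from the others of its group was found in 21 of 186 values tested in sgLuc and sgEzh2 + sgRunx1. The nominal rate of the cut-off is about 1 in 20 for independent values with a normal spread. Values of the same library are related, so that rate does not hold strictly here. In sgLuc, replicate 5 had 57.2 M counts and a Pcdh7 level of 1.22 CPM, and replicate 6 a Myh10 level of 4.28 CPM. Replicate 4 had 1.00 CPM of Hmga2 and lower mean log2 CPM of the lists megakaryocyte and platelet (−0.0283), inflammation and NF-kB (4.00) and immediate early and heat shock (4.21). Replicate 3 had 139 CPM of Xist, 64.5 of Eif2s3y, 39.8 of Ddx3y and 34.0 of Afap1, and a primary granule level of 9.59. In sgEzh2 + sgRunx1, replicate 2 had 54.2 CPM of Bcor, 1660.0 of C4b and 0.121 of Fcer1a, and levels of 1.28 for the plasma cell list, −2.14 for T and NK cells and 7.01 for oxidative phosphorylation. Replicate 3 had 0.243 CPM of Ms4a1, 62.6 of Ces2g and 32.8 of Zfand2a.

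The effect of the Runx1 guide differed with the Ezh2 guide for 93 genes by the edgeR test of the interaction, among them Chst1 (3.22 on the log2 scale), Trf (2.52), Ctsc (2.05), Sytl2 (−6.48) and Il12rb1 (−4.36). With the Bcor guide it differed for 568 genes, among them Vcan (8.07), Apoc2 (4.51), Oas1g (4.16), Iigp1 (−8.50), Emp1 (−6.63) and Casc4 (−6.36). The sex-linked list was called in both (camera adjusted p 2e-07 and 4.54e-07 with an estimated correlation), which follows from the arithmetic of an interaction in which only sgLuc held Y-linked reads. Chst1 was lower and Emp1 higher in every edited group than in sgLuc. By the same arithmetic an offset of sgLuc alone would give each an interaction of the observed sign. Over leave-one-out the counts ran from 6 to 322 and from 89 to 1660. No gene named for the Ezh2 guide kept its call in all 16 omissions. Both interactions are confounded with sex.

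For 79 genes changed the same way in all 5 comparisons against sgLuc, a candidate explanation is a property of the sgLuc mice or libraries other than their guide. Dosage of X and Y could account for the 10 members on these chromosomes (Fisher's exact p 0.000219, two-sided) but not by their own copy number for the 69 elsewhere, on which effects of X- and Y-linked regulators were not tested. A donor chromosome segment around Gt(ROSA)26Sor stays a hypothesis: 12 members lay within 25 Mb (7 without NK receptor genes and Gt(ROSA)26Sor; Fisher's exact p 0.00145), but this window was placed on a member and sized after the genes were seen, so the p is no independent test. Sex, or a batch or donor genotype that follows it, cannot be told apart from the guides for the rest, since 0 libraries outside sgLuc held Y-linked reads. Many higher members were predicted genes, pseudogenes or mitochondrial genes, and a difference in library preparation or mapping was not tested. An effect common to all edits stays open and untested.

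sgEzh2 + sgLuc replicate 3 stood apart, and 14 of 20 T and NK list members were highest in it of all 22 libraries, so cells of the T lineage are a candidate source. The B cell gene Ms4a1 was also highest in this library (289 CPM against 0 to 94.7 in the other 21). Cd79a, at 322 CPM, lay inside the range of the others (0.726 to 627). Whether B cells add to the difference of this library was not tested. With 0 reads of Y-linked genes, sgEzh2 + sgLuc replicate 3 was no exchanged sgLuc sample. An exchange with another group without a guide against Ezh2 cannot be told apart, since its 57.6 CPM of Ezh2 lay under the lowest such library (66.6) by more than the SD of its group (6.97), but in a library of unlike cells, where Ezh2 levels do not compare. A T cell disease of this mouse is a hypothesis for which the labels give no status.

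Bcor mRNA was higher in sgBcor + sgLuc, against the direction a guide-induced loss of mRNA might give. B-lineage content does not account for replicate 2, which held 111 CPM at a B cell progenitor level of 1.54, while the 3 libraries without sgBcor that reached the mean level of the group (5.09) held at most 65.0. For replicates 1 and 3 it stays open, since no library of another group reached their level. The pair of X chromosomes does not account for the rise, since libraries without Y reads and without sgBcor had a median of 1.07 times the sgLuc median, with only sgEzh2 + sgLuc replicate 3 apart from it at 155 CPM, and neither does normalization, with a lowest fold of 2.43 over 3 other scalings and the DESeq2 test. A change in transcription or stability of the edited mRNA is a hypothesis that these counts cannot test.

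In each comparison of a pair of groups only the real split gave as many genes, in fits of only the groups compared. The share of such splits was under 0.05 but for the last 2 below, with no adjustment over the comparisons. The main counts, from the fit of all libraries, were not tested this way. In the comparisons against sgLuc the real split also parted libraries with and without Y-linked reads. A high count there cannot tell the guides from sex. The real count and the highest of the other splits were 2991 and 3 for sgRunx1 + sgLuc, 99 and 0 for sgEzh2 + sgLuc, 1155 and 4 for sgBcor + sgLuc and 2634 and 2 for sgBcor + sgRunx1 (84 splits each), and 3180 and 2 for sgEzh2 + sgRunx1 (100 splits), all against sgLuc. They were 1592 and 5 for sgEzh2 + sgRunx1 against sgRunx1 + sgLuc, 588 and 1 against sgEzh2 + sgLuc and 1284 and 0 against sgBcor + sgRunx1 (35 splits each), and 76 and 2 for the interaction of Ezh2 and Runx1 (100 splits). For the interaction of Bcor and Runx1 they were 1063 and 364 (100 splits). In both interactions the labels were shuffled over all groups compared. This also breaks the effects of the single guides, so these splits cannot tell whether an interaction arose by chance. For sgBcor + sgRunx1 against sgRunx1 + sgLuc (6 and 1) and against sgBcor + sgLuc (854 and 0) the 10 splits are too few for a share under 0.05.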

How the results depend on the processing

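The fit without sgEzh2 + sgLuc replicate 3 in comparisons that do not use its group and the counts without genes on X and Y were chosen after seeing the data, all other settings before. DESeq2 size factors, library sizes without abundant genes, the stricter filter and the removal of X and Y genes left every count of called genes within 1.5 times its value. Of the values of named genes per comparison, called or not, 562, 555, 529 and 530 kept direction and side of the threshold in these settings, and 11, 18, 3 and 5 lost the call. The DESeq2 test kept 549 and lost 1, FPKM 478 and 96, no low-count filter 453 and 120, voom with quality weights 441 and 120, the groups compared alone 401 and 156, the fold threshold 253 and 321, and leave-one-out, here always with the omission of sgEzh2 + sgLuc replicate 3, 4184 and 1155. Of the 140 list calls 137 remained with either other scaling, 58 with fry and 8 with an estimated correlation. Cell content, sex and sequencing depth were not modelled, depth limits genes near 0 counts, and where a group kept 2 libraries the spread came from all groups. The cause of the shifts below was not tested.

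Counts of called genes are listed in the order sgRunx1 + sgLuc, sgEzh2 + sgLuc, sgBcor + sgLuc, sgEzh2 + sgRunx1 and sgBcor + sgRunx1 against sgLuc, sgEzh2 + sgRunx1 against sgRunx1 + sgLuc and against sgEzh2 + sgLuc, sgBcor + sgRunx1 against sgRunx1 + sgLuc and against sgBcor + sgLuc, the doubles, and the interactions of Ezh2 and of Bcor with Runx1. The main counts were 1434, 1456, 558, 1787, 2547, 33, 2228, 219, 2161, 1245, 93 and 568. A fold threshold of 2 gave 357, 127, 48, 513, 673, 2, 729, 3, 468, 150, 4 and 16, as a larger change was asked for. Leave-one-out gave 515 to 2647, 191 to 2624, 120 to 1484, 1176 to 3163, 1427 to 4133, 5 to 570, 1383 to 2623, 18 to 913, 1093 to 3827, 462 to 2726, 6 to 322 and 89 to 1660. The upper ends other than 2624, 2623 and 322 came without sgEzh2 + sgLuc replicate 3, which is in none of those groups, and within the groups compared they were 1420, 511, 1714, 2383, 28, 302, 1818, 1110 and 750.

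Settings that moved only part of the counts were these. The DESeq2 test gave 2226 for sgRunx1 + sgLuc and 1238 for sgBcor + sgLuc against sgLuc, 402 and 813 for the doubles with Ezh2 and with Bcor against sgRunx1 + sgLuc, 2019 between the doubles, and 588 and 1311 for the interactions. Limma voom with quality weights gave 6312, 3807 and 4846 for sgRunx1 + sgLuc, sgBcor + sgLuc and sgEzh2 + sgRunx1 against sgLuc, 4318 and 3829 for sgEzh2 + sgRunx1 against its singles, 1335 for sgBcor + sgRunx1 against sgRunx1 + sgLuc, 2175 between the doubles, and 2364 and 2697 for the interactions. FPKM gave 185 for sgEzh2 + sgRunx1 against sgRunx1 + sgLuc and 183 for the interaction of Ezh2 and Runx1. No low-count filter, with more genes tested, gave 96 for sgBcor + sgRunx1 against sgRunx1 + sgLuc and 45 and 252 for the interactions. Only the groups compared gave 2991, 99, 1155 and 3180 for sgRunx1 + sgLuc, sgEzh2 + sgLuc, sgBcor + sgLuc and sgEzh2 + sgRunx1 against sgLuc, 1592 and 588 for sgEzh2 + sgRunx1 and 6 and 854 for sgBcor + sgRunx1 against their singles, and 1063 for the interaction of Bcor and Runx1.

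The samples share only replicate numbers. Deviations from the group means correlated with r −0.135 to 0.0965 (median 0.0144) in 46 pairs with the same number and −0.184 to 0.181 (median −0.0106) in 152 others, and 5 of 22 libraries were closest to 1 of their own number. With the replicate block the counts were 535, 153, 148, 877, 1463, 16, 1459, 98, 1438, 777, 12 and 76 in the order above, 331 values of named genes kept direction and side of the threshold, called or not, 240 were no longer called, 130 list calls remained and 10 ended, and Bcor in sgEzh2 + sgRunx1 against sgLuc (−0.0134), Ezh2 in sgRunx1 + sgLuc against sgLuc (0.00164) and Runx1 in sgBcor + sgRunx1 against sgRunx1 + sgLuc (0.00597) changed sign.

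The direction turned for 32 values of single genes, none of them called in the setting that turned it (adjusted p at least 0.237 by the test of each setting). With all libraries edgeR had called some of these genes. They were Il4 (3.63), Cdkn2b (2.28) and Epop (1.535) in sgEzh2 + sgLuc against sgLuc, and Dlk1 (−4.43) in sgEzh2 + sgRunx1 against sgEzh2 + sgLuc. For Ezh2 in sgRunx1 + sgLuc against sgLuc the value was 0.00742 with voom, 0.00497 with no filter, 0.000856 with the stricter filter and −0.0495 to 0.0358 over leave-one-out (positive without sgLuc replicate 2, 3 or 4 or sgRunx1 + sgLuc replicate 1 or 2). For Bcor there it was −0.123 to 0.00608. In sgEzh2 + sgLuc against sgLuc, Il4 was at −1.02 with voom and −1.46 to 4.19 over leave-one-out, Epop at −0.381 and −0.198 to 2.01, and Cdkn2b at −0.117 with voom. The negative ends came without replicate 3. For Runx1 in sgEzh2 + sgRunx1 against sgRunx1 + sgLuc voom gave −0.0209 and leave-one-out −0.115 to 0.161. For Dlk1 in sgEzh2 + sgRunx1 against sgEzh2 + sgLuc voom gave 1.88 and leave-one-out −5.51 to 0.927. For Runx1 in sgBcor + sgRunx1 the values were 0.0151 (only the groups compared) and −0.148 to 0.131 (leave-one-out) against sgRunx1 + sgLuc, and −0.165 to 0.11 against sgBcor + sgLuc. Between the doubles Runx1 ranged from −0.103 to 0.166, and Bcor in the interaction of Ezh2 and Runx1 from −0.751 to 0.0281.

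Without sgEzh2 + sgLuc replicate 3 the direction of 6 lists turned by the camera test (adjusted p with that omission, then the range over leave-one-out). In sgEzh2 + sgLuc against sgLuc it was 0.00987 for MYC and ribosome biogenesis (2.46e-05 to 0.0395). In sgEzh2 + sgRunx1 against sgEzh2 + sgLuc it was 0.00203 for neutrophil granule (6.68e-07 to 0.00203), 0.865 for cell cycle (0.00477 to 0.865) and 0.129 for cytosolic ribosomal proteins (1.22e-07 to 0.129). In the interaction of Ezh2 and Runx1 it was 0.000265 for neutrophil granule (3.66e-06 to 0.0118) and 0.851 for cytosolic ribosomal proteins (1.28e-09 to 0.851). For neutrophil granule in this interaction camera called the list higher with all libraries, with a median log2 difference of 0.132 and a mean of −0.00479 over the members.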

Other observations

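The values in this part were chosen after seeing the data.

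Antigen receptor segments of sgEzh2 + sgLuc replicate 3 were dominated by single segments. Trbv13-1 took 81.8% of its 10137 counts over T cell receptor beta V segments (exact 95% interval 81.1 to 82.6), and Trav12-3 took 91.1% of its 3252 counts over alpha V segments (90.1 to 92.1). In the other 21 libraries the beta segments held 6 to 914 counts, with 14.9 to 83.3% (median 29.4%) on the top segment, and the alpha segments held 5 to 249 counts, with 7.73 to 55.0% on the top segment. Immunoglobulin segments of the same library were spread more widely, with 17.5% of 31657 heavy chain counts on Ighv2-3 and 26.8% of 44874 kappa counts on Igkv1-117. Transcripts of CD4 T cells stood high in it, with Cd4 at 123 CPM (0.194 to 30.7 in the other 21 libraries), Izumo1r at 642 (0 to 3.74), the costimulatory receptor Icos at 312 (0.0556 to 5.62) and Gata3 at 131 (0.242 to 7.85), while Cd8a stood at 15.8 (0 to 12.8). Myc stood at 225 CPM (50.5 to 151). No test was made of how often single mice hold such a pattern.

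B cell progenitor genes differed within sgBcor + sgLuc, with mean log2 CPM of 6.29, 1.54 and 7.43 in its replicates against 2.73 to 5.20 in sgLuc. The first and the last of these were above every library of the other groups, the highest of which was 5.75.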
